A study of Homo sapiens with 24 samples.

How the data were processed

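RNA was measured by sequencing in VCaP, a human prostate cancer cell line that carries the TMPRSS2-ERG fusion. Per the labels, the cells carried a first lentivirus with a Tet-inducible short hairpin against ERG and a second lentivirus with either a hairpin against ERF (shERF) or a hairpin called shNT, each selected with its own antibiotic. Doxycycline (dox) at 100 ng/mL, the inducer of the ERG hairpin, and dihydrotestosterone (DHT), the active androgen, at 1 nM for 16 hours were given alone, together or not at all (vehicle). This made 8 groups of 3 libraries, 24 in all. The 3 libraries of a group came from separately plated sets of cells of one line, so p-values measure the spread between platings. Replicates were numbered in accession order, and no batch was given.

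The deposited table held, per the file header, counts scaled by the authors per library, a signal in arbitrary units that was not divided by gene length, for 22341 genes with their identifiers and symbols. Build hg19, Picard, HTSeq and DESeq are named without versions or roles, per the submitters' processing notes; the aligner, the annotation release and the use of strand are not given in the sources used here. In all 24 columns the smallest value was 1, and the value minus 1 was a whole multiple of a fixed step, with a largest deviation of 1.54e-09 against a tolerance of 1e-08, so each value was taken as reads times a library step plus 1. Recovered totals ran from 17443672 to 26470909 reads in genes per library. With strand not stated, reads of overlapping antisense genes could not be told apart. Reads of near-identical genes (the UGT2B family, KLK2 and KLK3, histone and HLA genes) may be split between copies, so the values of single members are uncertain. Of the 22341 identifiers, 21571 were found in GENCODE 29, which was used for chromosomes alone; its build differs from hg19, so no coordinates are given.

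Values were transformed to log2(value + 1), so fold changes are on that scale and understate the change of low genes. Genes with a value of at least 10 in at least 3 libraries were tested, which kept 16915 and left out 5426. One limma model (limma 3.58.1, R 4.3.3) with a mean per group, a shared spread over the 24 libraries (16 residual degrees of freedom) and a prior variance with a trend gave 12 comparisons of groups of 3 that differ in 1 factor, and 4 interactions. An interaction is the difference between 2 log2 fold changes. All adjusted p-values are Benjamini-Hochberg values. Those of genes come from limma's two-sided test, over all genes of a comparison, and a gene was called at an adjusted p below 0.05. On simulated reads with known changed genes, the comparison of dox in shNT cells recovered 71.6% of genes changed 1.5-fold, 82.1% at 2-fold and 95.3% at 4-fold, with 3 false calls among 16589 genes. The simulated interaction of dox and shERF recovered 58.5%, 78.8% and 87.9% at the same folds, with 3 false calls among 16588 genes. The simulation changed few genes (67, 67 and 64 at these folds for dox) in a single group. It used the same noise in all groups and known scaling. In the data 26% to 53.7% of genes were called in comparisons of 2 groups, and spread differed between groups. These rates may therefore not carry over.

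Groups, comparisons, 17 gene lists and the rule for named genes were fixed before the data were examined. The rule took ERG and ERF for their own hairpins; the 6 highest and 6 lowest fold changes among called genes with a symbol, a mean value of at least 100 and, for 2 groups, no overlap of their libraries; up to 4 members with the smallest p of each list that passed and of the androgen-induced, ERG/ETS-linked and ERK-output lists in every comparison; and preset androgen-induced genes, among them KLK3, KLK2, TMPRSS2 and FKBP5, everywhere. Some genes that the rule takes are not reported here. Chance alone separates 3 libraries from 3 in 10% of genes. The lists, written from textbook knowledge, were androgen-induced, androgen-repressed, ERG/ETS-linked, ERK-output, ETS-family, cell-cycle, luminal prostate, basal or mesenchymal, neuroendocrine, interferon-response, cholesterol-synthesis, unfolded-protein and amino-acid stress, hypoxia and glycolysis, mitochondrial-genome, p53-response and histone genes, and markers of other cell types (stroma, endothelium and leukocytes). Each was tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 272 tests, and again with a correlation estimated per list. Genes that rose or fell with dox were tested as sets in the same way in shERF comparisons, adjusted over the 8 sets, a choice made after their values were seen. A list score, the mean centred log2 value of its members, was compared per factor by permuting labels within the 4 strata set by the other factors, over all 160000 relabellings and 51 tests; 1.3e-05 was the smallest p that these gave.

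No replicates were merged, since all 24 replicate pairs differed by more than sampling noise, with a chi-square per degree of freedom between 1.64 and 25.4. Their Pearson correlations across genes lay between 0.9917 and 0.9955. Alternatives covered the pseudocount, the filter, TMM factors, scaling to one total per library, the variance prior, the libraries in the model, the set test, each replicate left out in turn, limma's voom on recovered reads and thinning of reads to the smallest library.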

Results

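Messenger RNA levels were measured in 24 libraries of VCaP cells, in 8 groups of 3. The groups crossed 3 factors: doxycycline (dox), which induces the ERG hairpin; the second hairpin, against ERF (shERF) or shNT; and DHT. The question named in the series title was how positive and negative ETS factors are balanced in prostate cancer cells. ERG is an ETS-family activator driven by the TMPRSS2 promoter in these cells, and ERF is an ETS-family repressor. Depth was 17443672 to 26470909 reads in genes per library, and the 4 groups with the fewest reads were shERF_dox and 3 of the 4 groups with DHT. The leading 3 principal components held 30.8%, 26.6% and 17.6% of the variance. Replicates of the shERF cells with dox were the least alike, with a chi-square per degree of freedom of 17.8 to 25.4 for their 3 pairs. Mitochondrial transcripts took 4.83% ± 1.35 (SD, n = 3) of reads in that group and 2.86% ± 0.146 in shNT vehicle cells.

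ERG (ENSG00000157554.14, chromosome 21) had a scaled read count of 14026.7 ± 529 (SD, n = 3) in shNT vehicle cells and 8606.5 ± 69.2 with dox, or 61.4% of vehicle. With DHT the counts were 16612.8 ± 376 without dox and 10151.8 ± 614 with it. In shERF cells ERG stood at 9855.6 ± 109 in vehicle, 5789.6 ± 160 with dox, 10741.1 ± 293 with DHT and 6033.9 ± 123 with both. ERG fell with dox in all 4 backgrounds, by log2 fold changes of -0.70 in shNT, -0.71 in shNT with DHT, -0.77 in shERF and -0.83 in shERF with DHT (SE 0.050 each). ERG was also lower in shERF than in shNT cells without dox, at -0.51 in vehicle and -0.63 with DHT, and with dox, at -0.57 and -0.75. ERF (ENSG00000105722.5, chromosome 19) had counts of 1010.8 ± 38.4 in shNT vehicle, 1015.4 ± 26.5 with dox, 1118.3 ± 83.2 with DHT and 1115.2 ± 62.8 with both. The 4 shERF groups had 392 ± 25.5, 413 ± 16, 359 ± 14 and 379 ± 8.99 in the same order, so ERF was lower in each shERF group, by -1.36, -1.29, -1.64 and -1.55 (SE 0.066). ERF did not pass the test for dox in any background, with adjusted p-values from 0.36 to 0.98.

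**Figure D1:**
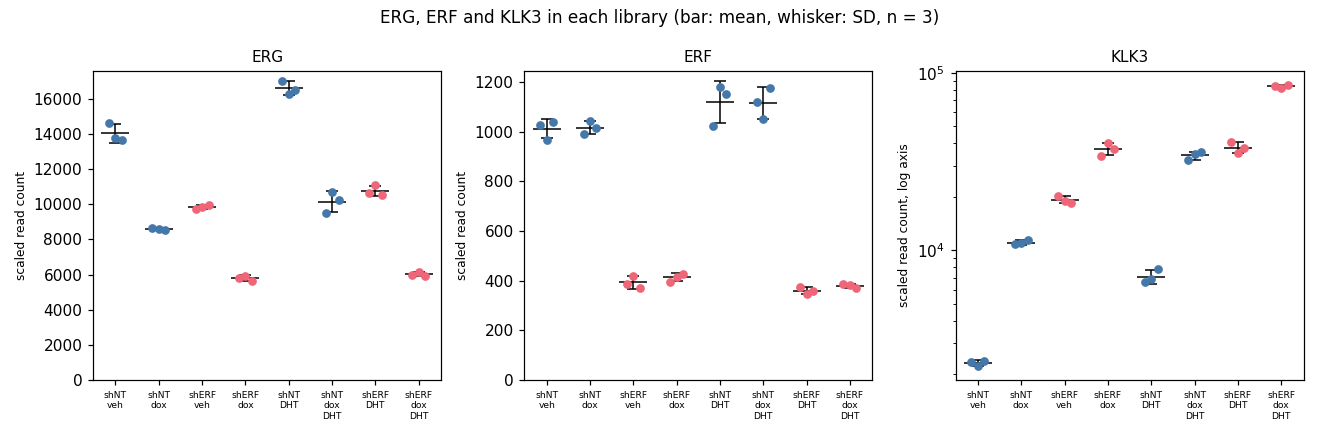
Scaled read counts of ERG, ERF and KLK3 (vertical axes, KLK3 on a log axis) in the 8 groups (horizontal axis), with 1 point per library, a bar for the mean and a whisker for the SD (n = 3). ERG means range from 5789.6 in shERF cells with dox to 16612.8 in shNT cells with DHT, and KLK3 means from 2315.0 in shNT vehicle cells to 83900.4 in shERF cells with dox and DHT.

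The comparisons of DHT with vehicle asked how the cells responded to androgen in each background. In shNT cells KLK3 (ENSG00000142515.10, chromosome 19), which encodes prostate-specific antigen, rose 3.06-fold (log2 1.61, SE 0.067), and FKBP5 (ENSG00000096060.10, chromosome 6), a chaperone of steroid receptors, rose 3.12-fold. STEAP4, a metalloreductase, rose most among the genes named, 48.8-fold (log2 5.61, SE 0.146), and NOV, SHH and WNT2, which encode secreted signalling proteins, fell with log2 fold changes of -3.64, -3.03 and -3.13. Of 21 androgen-induced genes 15 rose and 2 fell in shNT cells, and adjusted over the list alone 16 rose and 2 fell; the list passed with an adjusted p = 3.1e-07 but had an adjusted p = 0.052 with an estimated correlation. Of 11 androgen-repressed genes 8 fell (8 adjusted over the list alone), with DDC, a decarboxylase, at -2.66 and UGT2B15, an androgen-glucuronidating enzyme, at -2.65. In shNT with dox, shERF and shERF with dox 14, 14 and 15 of 21 androgen-induced genes rose, with an adjusted p = 0.031, 0.1 and 0.065 with an estimated correlation, and 7, 9 and 8 of 11 androgen-repressed genes fell. KLK2 rose by 0.50 in shNT cells and by 0.44 with dox, but did not pass in shERF cells (0.05, adjusted p = 0.61) or in shERF cells with dox (0.12, adjusted p = 0.23).

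Cholesterol-synthesis genes rose with DHT in every background, 16, 15, 17 and 17 of 17 in shNT, shNT with dox, shERF and shERF with dox (16, 16, 17 and 17 adjusted over the list alone). INSIG1, which retains the sterol sensor, rose by 1.85, 1.49, 1.64 and 1.53. Hypoxia and glycolysis genes rose with DHT, 11 of 12 in shNT cells (11 adjusted over the list alone), among them PGK1 at 1.10 and LDHA at 0.92. The adjusted p of that list with an estimated correlation was 0.048 in shNT cells and 0.21, 0.065 and 0.062 in shNT with dox, shERF, and shERF with dox. Cell-cycle genes went opposite ways: 19 of 25 rose in shNT cells and 23 of 25 in shERF cells (20 and 23 adjusted over the list alone), with E2F1, an S-phase transcription factor, at 1.07 in shNT and MCM6, a subunit of the replicative helicase, at 1.28 in shERF cells. In shNT cells with dox, 18 of 25 fell and none rose (19 and 1 adjusted over the list alone), with the helicase subunits MCM4 and MCM2 at -0.75 and -0.73. In shERF cells with dox the list did not pass (median -0.14, adjusted p = 0.05). EGR1 and FOS, immediate early genes of the ERK-output list, fell by 2.01 and 1.95 on the log2 scale in shNT cells, where the list itself did not pass. That list fell in shNT cells with dox, with 7 of 16 lower and 4 higher (8 and 4 adjusted over the list alone), shERF cells, and shERF cells with dox, but had an adjusted p = 0.3, 0.25 and 0.24 with an estimated correlation; in shNT cells with dox its adjusted p was 0.066 under one total per library and 0.051 without shNT_dox replicate 2. Unfolded-protein and amino-acid stress genes were higher in all 4 backgrounds at the preset correlation, 7, 8, 10 and 9 of 16, with an adjusted p = 0.36, 0.19, 0.088 and 0.093 with an estimated correlation. In shNT cells that call ended under one total per library (adjusted p = 0.087) and without shNT_veh replicate 2 (0.067) or shNT_DHT replicate 3 (0.061). Luminal prostate genes passed only in shNT cells with dox, with 9 of 13 higher (10 adjusted over the list alone) and an adjusted p = 0.029 with an estimated correlation. The p53-response list passed only in shERF cells, with 5 of 12 lower and 2 higher and an adjusted p = 0.052 with an estimated correlation.

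DHT changed 7366 genes in shNT cells (3925 higher, 3441 lower), 6361 in shNT with dox (3209 and 3152), 9029 in shERF (4498 and 4531) and 8170 in shERF with dox (4154 and 4016). The balance of directions depended on the scaling: with one total per library the percentage of changed genes that were higher went from 53.3 to 36.8 in shNT, 50.4 to 33.9 in shNT with dox and 50.8 to 34.1 in shERF with dox, where the median log2 change of all genes moved from -0.011 to -0.119. Mitochondrial-genome transcripts were higher with DHT in shNT, shNT with dox and shERF with dox, 10, 7 and 13 of 13 genes, with an adjusted p = 0.52, 0.56 and 0.53 with an estimated correlation. In shERF cells with dox the median went from 0.57 to 0.23 without shERF_dox replicate 3 (adjusted p = 0.048), a library with a score of -0.640 against 0.345 and 0.204 for the others of its group.

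The comparisons of dox with vehicle asked what changed when the ERG hairpin was induced; no library had dox without that hairpin. In shNT cells KLK3 rose 4.77-fold (log2 2.25, SE 0.067) and TMPRSS2 (ENSG00000184012.7, chromosome 21), an androgen-induced serine protease, 2.32-fold (log2 1.21, SE 0.055). In shERF cells KLK3 rose 1.93-fold and TMPRSS2 1.73-fold. TMPRSS2 reads cover transcripts from intact copies and may include fusion reads, which were not separated. Of 17 ERG/ETS-linked genes 12, 14, 11 and 12 fell in shNT, shNT with DHT, shERF and shERF with DHT (the same numbers adjusted over the list alone), with adjusted p = 0.008, 0.011, 0.0078 and 0.013 with an estimated correlation. PLA1A, a phospholipase gene, fell by 1.61, 1.73, 1.36 and 1.34 on the log2 scale, and PLAT, tissue plasminogen activator, by 2.03, 1.31, 2.32 and 1.51. ADAMTS1, a secreted metalloprotease, went against the list and rose by 3.20, 3.16, 1.93 and 1.79. SLPI, a secreted protease inhibitor, fell 15.8-fold in shNT and 18.4-fold in shERF cells, and CRISPLD1 rose 9.81-fold and 8.59-fold.

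With DHT present, all 25 cell-cycle genes fell with dox in both shNT and shERF cells (25 of 25 adjusted over the list alone), with medians of -0.70 and -0.55 and an adjusted p = 0.0014 with an estimated correlation in each. MCM6 and MCM3, helicase subunits, fell by 1.34 and 1.27 in shNT and by 1.43 and 1.30 in shERF cells on the log2 scale. Without DHT 9 of 25 fell and 1 rose in shNT cells (10 and 1 adjusted over the list alone), with an adjusted p = 0.3 with an estimated correlation, and the call ended at adjusted p = 0.066 without shNT_veh replicate 1 and 0.062 without shNT_dox replicate 1. In shERF cells without DHT the list did not pass, with 2 of 25 higher, 2 lower and a median of -0.01 (adjusted p = 0.71). Luminal prostate genes rose with dox, 7, 10, 5 and 8 of 13 in the same 4 backgrounds (7, 10, 5 and 8 adjusted over the list alone), among them SLC45A3, which encodes prostein, by 1.77, 2.06, 1.63 and 2.10; the adjusted p was 0.052, 0.0094, 0.052 and 0.043 with an estimated correlation. Androgen-induced genes rose in 12, 14, 11 and 13 of 21 cases, with an adjusted p = 0.047, 0.051, 0.053 and 0.084 with an estimated correlation. Cholesterol-synthesis genes rose in 15, 13, 13 and 9 of 17 cases, with an adjusted p = 0.018, 0.088, 0.036 and 0.33 with an estimated correlation. The ERK-output list fell in shNT cells and in shNT cells with DHT (8 and 9 of 16), with an adjusted p = 0.13 and 0.21 with an estimated correlation. In it DUSP4, an ERK phosphatase, fell by 2.07, 2.99, 2.19 and 3.16 on the log2 scale in the 4 backgrounds. Other lists passed with dox at the preset correlation alone. Unfolded-protein and amino-acid stress genes were higher in shNT, shNT with DHT and shERF, 9, 10 and 6 of 16, with an adjusted p = 0.32, 0.33 and 0.38 with an estimated correlation. That call ended without shNT_veh replicate 2 in shNT cells (adjusted p = 0.051), and without shERF_veh replicate 3 (0.19) or shERF_dox replicate 2 (0.16) in shERF cells. Hypoxia and glycolysis genes fell in shNT cells with DHT, 10 of 12, with an adjusted p = 0.21 with an estimated correlation. Neuroendocrine genes rose in shERF cells, 5 of 11, with an adjusted p = 0.26 with an estimated correlation, and the call ended without shERF_veh replicate 3 (adjusted p = 0.12) or shERF_dox replicate 2 (0.078).

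Dox changed 4875 genes in shNT cells (2677 higher, 2198 lower), 7366 in shNT with DHT (3713 and 3653), 4394 in shERF (2441 and 1953) and 7143 in shERF with DHT (3879 and 3264). The 4394 became 2718 when only the libraries of that comparison entered the model. Signs of RNA composition moved with dox as well: 7 of 7 histone genes rose in shNT cells with and without DHT, with HIST2H2BE at 1.34 without and 2.06 with DHT. In shERF cells 3 of 7 rose, with an adjusted p = 0.33 with an estimated correlation, and the call ended without shERF_dox replicate 2 (adjusted p = 0.22) or shERF_veh replicate 3 (adjusted p = 0.12). In shERF cells with DHT 6 of 7 rose (7 adjusted over the list alone), with an adjusted p = 6.2e-04, or 0.1 with an estimated correlation. Mitochondrial-genome transcripts were higher with dox in shNT, shNT with DHT and shERF with DHT, 13, 9 and 10 of 13 genes, with an adjusted p = 0.45, 0.61 and 0.59 with an estimated correlation. In shNT cells with DHT that call ended without shNT_dox_DHT replicate 3 (adjusted p = 0.084). In shERF cells without DHT none of the 13 was called and the median was -0.14 (adjusted p = 0.57), and it became 0.18 without shERF_dox replicate 3 (adjusted p = 0.023) and -0.33 without replicate 1 (adjusted p = 0.026). The score of 4 measured markers of other cell types was 0.66 higher with dox (adjusted exact permutation p = 4.6e-05), while the list passed in no comparison with camera (shNT cells, 2 of 4 higher, adjusted p = 0.067). The pair that rose, named after their values were seen, were the collagen gene COL1A1 at 0.99 and LUM, which encodes lumican, at 2.46, both at low counts of 106.8 and 25.2 in shNT vehicle cells.

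The comparisons of shERF with shNT asked what changed with lower ERF; each hairpin was present in 1 infected and selected population. KLK3 was 8.31-fold higher in shERF vehicle cells (log2 3.06, SE 0.067), 5.34-fold with DHT, 3.37-fold with dox and 2.45-fold with both. TMPRSS2 fell with DHT, dox and both (-0.39, -0.51 and -0.61) and was at -0.09 in vehicle (adjusted p = 0.19). ID1, an inhibitor of helix-loop-helix transcription factors, was among the highest, with log2 fold changes of 5.08, 4.98, 4.12 and 3.47. IGFBP3, an insulin-like growth factor binding protein, rose by 4.47 in vehicle and 4.76 with DHT, and SLC16A3, a lactate transporter, fell by 3.65 and 2.80 on the log2 scale. The androgen-induced, androgen-repressed and ERG/ETS-linked lists passed in none of the 4 with camera, which compares a list with all other genes. Their scores, which are not compared with other genes, were higher with shERF in 4 of 4 strata, by 0.28, 0.63 (adjusted exact permutation p = 2.5e-05 each) and 0.09 (adjusted exact permutation p = 2.8e-04). A score is a mean and need not stand for most members. The androgen-induced list had medians of -0.06, 0.06, -0.03 and 0.04 in vehicle, DHT, dox and both. Of its 21 genes 7, 9, 6 and 6 were higher and 5, 6, 9 and 7 lower. Medians of the androgen-repressed list were 0.12, 0.43, 0.64 and 0.59. Those of the ERG/ETS-linked list were -0.07, 0.00, -0.08 and -0.03. Of its 17 genes 6, 7, 7 and 7 were higher and 6 lower in each, so its higher score does not stand for most members.

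Hypoxia and glycolysis genes were lower in shERF cells, 11 of 12 in vehicle, 11 with DHT, 10 with dox and 9 with both (the same numbers adjusted over the list alone), with an adjusted p = 0.047, 0.07, 0.043 and 0.2 with an estimated correlation. VEGFA, an angiogenic factor, was at -2.31, -1.41, -1.82 and -1.01, and PDK1, a pyruvate dehydrogenase kinase, at -2.00, -1.41, -2.07 and -1.25. Unfolded-protein and amino-acid stress genes were higher in 16, 15, 14 and 15 of 16 cases (16, 15, 14 and 15 adjusted over the list alone), with an adjusted p = 0.029, 0.013, 0.017 and 0.0094 with an estimated correlation. HERPUD1, an endoplasmic reticulum stress gene, was at 0.60, 1.20, 0.43 and 0.98. Interferon-response genes were higher in 10, 7, 12 and 11 of 16 cases (11, 6, 12 and 11 adjusted over the list alone) and none was lower, with an adjusted p = 0.008, 0.044, 0.008 and 0.0078 with an estimated correlation. IFIT3, an antiviral gene, was at 2.04, 1.93 and 1.80 in vehicle, DHT and dox. Cholesterol-synthesis genes were higher in 15, 16, 14 and 16 of 17 cases, with SC5D, a sterol desaturase, at 1.52, 1.34, 1.07 and 0.85, and an adjusted p = 0.052, 0.031, 0.052 and 0.036 with an estimated correlation.

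Neuroendocrine genes were lower in 6, 8, 7 and 7 of 11 cases, with an adjusted p = 0.24, 0.11, 0.21 and 0.1 with an estimated correlation; ENO2, a neuronal enolase, was at -1.81, -2.39, -1.66 and -1.77, and in vehicle the list call ended without shERF_veh replicate 3 (adjusted p = 0.09). Basal or mesenchymal genes passed with dox alone, with 3 of 6 measured genes higher, among them KRT14, a basal keratin, at 2.11, and an adjusted p = 0.098 with an estimated correlation; the call ended at adjusted p = 0.062 without shNT_dox replicate 3 and 0.052 without shERF_dox replicate 2. SPRY4 and FOS of the ERK-output list, a feedback inhibitor and an immediate early gene, rose in vehicle by 3.37 and 2.04. The list passed in none of the 4 with camera, while its score was 0.35 higher in 4 of 4 strata (adjusted exact permutation p = 2.5e-05). Its medians were 0.24, -0.04, 0.07 and 0.19 in vehicle, DHT, dox and both. Of its 16 genes 8, 5, 6 and 6 were higher and 5, 4, 3 and 3 lower. Cell-cycle genes were lower in vehicle and with dox, 15 and 13 of 25 (15 and 13 adjusted over the list alone), with an adjusted p = 0.0011 and 0.02, or 0.15 and 0.3 with an estimated correlation. The p53-response list passed with dox, with 6 of 12 higher, 1 lower and an adjusted p = 0.061 with an estimated correlation. ETS-family genes as a list passed in no comparison; in shERF vehicle cells 6 of 19 were higher and 6 lower, with a median of 0.01 and a test direction of down (adjusted p = 0.8). shERF changed 7884 genes in vehicle (4076 higher, 3808 lower), 9082 with DHT (4571 and 4511), 6278 with dox (3166 and 3112) and 7708 with both (4037 and 3671). Histone genes were higher in vehicle, DHT and dox, 7, 6 and 4 of 7, with an adjusted p = 0.06, 0.091 and 0.28 with an estimated correlation, and did not pass with both (adjusted p = 0.069). Mitochondrial-genome transcripts were higher in vehicle, 13 of 13, with an adjusted p = 0.41 with an estimated correlation, and did not pass in the other 3.

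**Figure D2:**
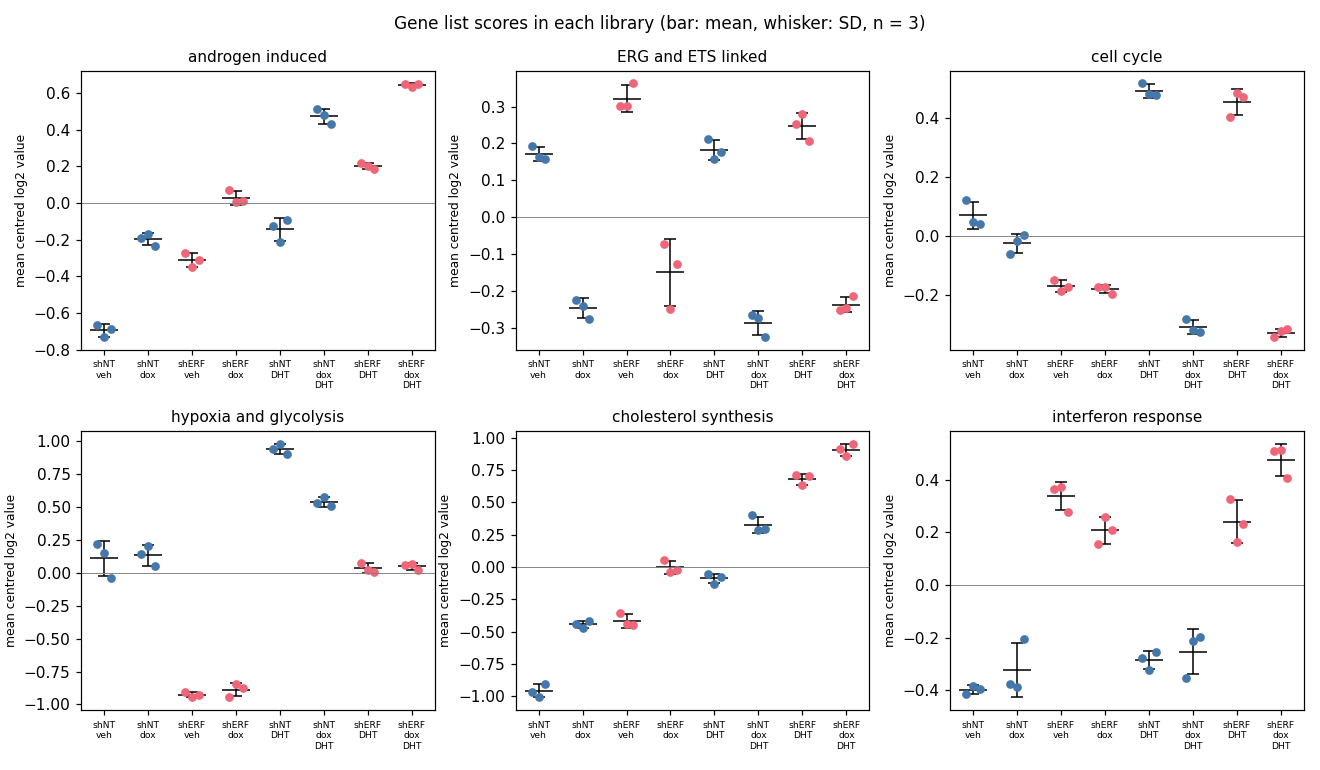
Scores of 6 gene lists, the mean of the members' centred log2 values (vertical axes), in the 8 groups (horizontal axes), with 1 point per library, a bar for the mean and a whisker for the SD (n = 3). The hypoxia and glycolysis score was 0.86 lower with shERF on average over the 4 strata and the cholesterol-synthesis score was 0.91 higher with DHT.

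The interaction of dox and shERF asked whether dox acted differently in shERF cells. On the log2 scale KLK3 rose less with dox in shERF cells, with a difference of -1.30 (SE 0.095) without DHT and -1.12 with DHT. In scaled counts its rise was larger there, from 19259.1 to 37258.3 against 2315.0 to 11039.7 in shNT cells without DHT. With DHT it went from 37897.4 to 83900.4 against 7104.0 to 34204.6. TMPRSS2 differed by -0.42 without DHT (SE 0.078) and was at -0.22 with DHT (adjusted p = 0.11), and ADAMTS1 differed by -1.27 and -1.37. TGM4, a prostate transglutaminase, had the lowest value among the genes named, -3.53 without and -3.44 with DHT. PLOD2, a collagen-modifying enzyme, had the highest without DHT, at 1.70, and ANGPTL4, an inhibitor of lipoprotein lipase, with DHT, at 1.73. Histone genes passed, with 2 and 3 of 7 lower (5 and 3 adjusted over the list alone). At the preset correlation alone, 4 more lists passed without DHT. They were mitochondrial-genome (median -0.63, with 13 of 13 lower over the list alone), cholesterol-synthesis (-0.08), cell-cycle (0.09) and androgen-induced genes (-0.05), with an adjusted p = 0.19, 0.33, 0.22 and 0.42 with an estimated correlation. The mitochondrial-genome median went to -0.29 without shERF_dox replicate 3 and to -0.83 without shERF_dox replicate 1, so its size rests largely on 1 library. The androgen-induced call ended under voom (adjusted p = 0.064) and in several fits without a replicate (up to 0.15 without shERF_dox replicate 2), and the cell-cycle call without shERF_dox replicate 2 (adjusted p = 0.052) or shNT_dox replicate 1 (0.05). With DHT they were cholesterol-synthesis (-0.16), androgen-induced (-0.08), hypoxia and glycolysis (0.34) and p53-response genes (0.11), with an adjusted p = 0.11, 0.3, 0.053 and 0.084 with an estimated correlation. The p53-response call ended without shNT_dox_DHT replicate 3 (adjusted p = 0.066) and the androgen-induced call without shNT_dox_DHT replicate 1 (0.059). Without DHT 341 genes differed (121 higher, 220 lower) and with DHT 926 (561 and 365), of which 60.6% were higher, or 46.1% of those changed under one total per library. Without shERF_dox replicate 2 the 341 became 800, and it was 217, 207 and 220 without shNT_veh replicate 1, shNT_veh replicate 2 and shNT_dox replicate 3.

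The interactions with DHT asked whether the androgen response differed with dox or with shERF. In shNT cells the cell-cycle list showed a lower DHT response with dox, with 23 of 25 genes called lower (25 adjusted over the list alone), a median difference of -0.65 and RRM2, a ribonucleotide reductase subunit, at -1.21 (SE 0.081). HPGD, a prostaglandin-degrading enzyme, and NCAPD3, a condensin subunit, had a higher response with dox, at 2.35 and 2.21. For KLK3 the difference in response was 0.02 (SE 0.095, adjusted p = 0.95). Luminal prostate genes passed with 4 of 13 higher (5 adjusted over the list alone, with 2 lower). In shERF cells without dox the DHT response on the log2 scale was lower than in shNT cells for KLK3 (-0.64), KLK2 (-0.45), TMPRSS2 (-0.30) and SPRY4 (-1.79), and higher for FKBP5 (0.64) and HK2, hexokinase 2 (1.63). In scaled counts KLK3 rose more in shERF cells, from 19259.1 to 37897.4 against 2315.0 to 7104.0. Of 12 p53-response genes 7 had a lower DHT response and 1 a higher one (7 and 1 adjusted over the list alone), with BBC3, a BH3-only gene, at -1.52 and an adjusted p = 0.04 with an estimated correlation. At the preset correlation alone, DHT by dox also passed for hypoxia and glycolysis (median -0.48) and histone genes (0.63), with an adjusted p = 0.052 and 0.13 with an estimated correlation. DHT by shERF did so for cell-cycle (0.29), cholesterol-synthesis (0.23), unfolded-protein and amino-acid stress (0.32) and mitochondrial-genome genes (-0.47), with an adjusted p = 0.13, 0.3, 0.088 and 0.56. DHT by dox called 1685 genes (704 higher, 981 lower) and DHT by shERF 4610 (2245 and 2365).

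**Figure D3:**
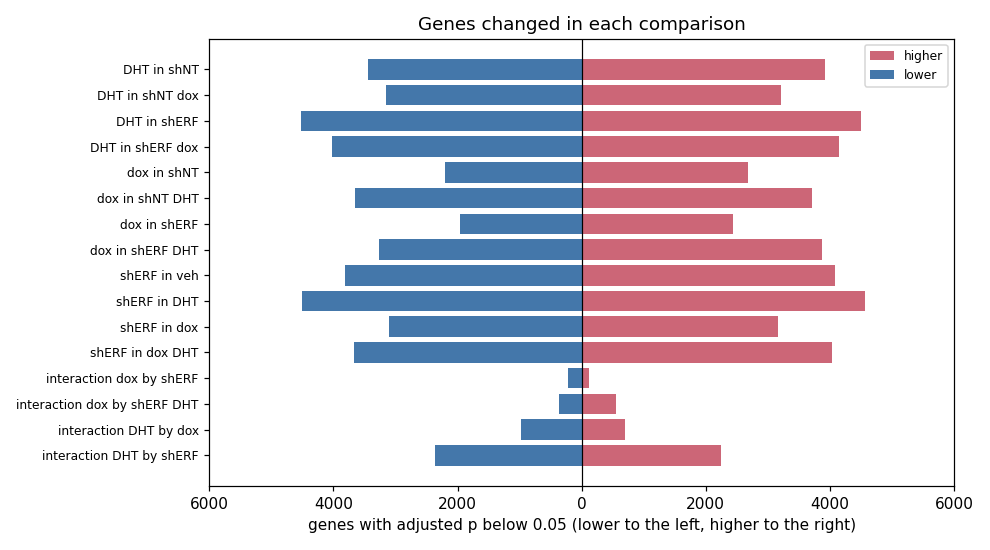
Number of genes with an adjusted p below 0.05 (horizontal axis) in each of the 16 comparisons (vertical axis), with genes higher to the right and genes lower to the left of 0. The comparison of shERF with shNT under DHT has the most, 9082, and the interaction of dox and shERF without DHT has the fewest, 341.

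Whether dox, which came with lower ERG, and shERF move the same genes in opposite directions was tested only between comparisons that share no library. Of genes called with dox in shNT cells, 50.5% had the opposite sign in shERF cells with dox and DHT against shNT cells with both, and 46.9% in shERF against shNT cells with DHT. Of genes called with dox in shNT cells under DHT, 39.2% had the opposite sign for shERF with dox and 34.5% for shERF in vehicle. The genes that rose with dox in shNT cells had median shERF changes of 0.05 and 0.10 in the first pair of comparisons and those that fell 0.05 and 0.01; under DHT the medians were 0.09 and 0.16 for genes that rose and -0.08 and -0.13 for genes that fell. Restriction to genes that dox changed at least 2-fold moved all of these medians but the last. Those that fell with dox in shNT cells had 0.57 (adjusted p = 2.2e-07, against 0.16 for all that fell) and 0.22 (0.07), and those that rose had 0.10 (0.39) and 0.34 (adjusted p = 3.0e-04). Under DHT the 2-fold genes that rose had 0.23 and 0.42, and those that fell had -0.01, with the test direction turned to up (adjusted p = 0.31), and -0.13 (0.29). Across 16915 genes, which are not independent replicates, the Pearson correlations of log2 fold changes were -0.04, 0.07, 0.11 and 0.23 in the same order. In the last pair 4192 genes were called in both comparisons, 3009 with the same sign (1717.1 for independent lists) and 1183 with opposite signs (1716.2 for independent lists). The same effect measured in other libraries was closer: the correlation was 0.67 for shERF in vehicle against shERF with dox and DHT and 0.68 for shERF with DHT against shERF with dox. For dox it was 0.63 in shNT against shERF with DHT and 0.56 in shNT with DHT against shERF, and for DHT 0.62 in shNT against shERF with dox.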

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

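The tests of dox itself, of lower ERG as the whole cause, of the TMPRSS2 promoter and of culture or selection, and all tests on thinned reads, were chosen only after the results were seen.

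The fall of cell-cycle genes with dox under DHT drew attention through a difference between groups: the DHT response of the list was lower with dox (median -0.65, adjusted p = 1.5e-04 with an estimated correlation, 23 of 25 genes). The libraries with dox and DHT held fewer reads. With reads thinned to one total the median difference was -0.62. Thinning keeps the expected scaled value of each gene, so this median could hardly move and the test does not decide on depth. Under one total per library the median difference was -0.64. That rescaling moved the median of all genes only from -0.003 to 0.007, so the list could hardly move and the test alone does not decide. A scaling factor shifts all genes of a library alike, while the list lay apart from all genes, which argues against the authors' scaling. An effect of dox itself cannot be told apart from the ERG hairpin, because the fall in shERF cells with DHT (median -0.55) came with both and no library had dox without that hairpin. Lower ERG, the difference the design names, may be a cause and was not tested apart from dox.

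ERG was lower in shERF cells, and 7884 genes differed from shNT cells in vehicle. If lower ERG were the whole cause, genes called for dox under DHT and for shERF would nearly all move the same way, but 28.2% of 4192 genes called in both moved in opposite directions in vehicle, and 35.4% of 3476 with dox. For genes called with dox without DHT, 1423 of 2830 called in both were opposite for shERF with dox and DHT. For shERF with DHT 1455 of 3209 were opposite. One effect measured in separate libraries gave 3.95% to 9.11% opposite. Genes moved by dox itself could also oppose, and no library had dox without the ERG hairpin, so lower ERG as the whole cause cannot be told apart from other causes. Lower activity of the TMPRSS2 promoter could lower fusion ERG, and TMPRSS2 was at -0.09 (SE 0.055) in vehicle against -0.51 for ERG. With DHT, dox and both TMPRSS2 was at -0.39, -0.51 and -0.61 against -0.63, -0.57 and -0.75 for ERG, a direction that goes with this explanation. However, DHT in shNT cells raised TMPRSS2 by 0.98 and ERG by 0.24, so TMPRSS2 did not follow ERG closely. Transcripts of intact TMPRSS2 copies keep the promoter explanation open. Lower ERF itself, the difference the design names, stays open and untested.

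Hypoxia and glycolysis genes were lower in shERF cells in all 4 comparisons at the preset correlation, but the list did not pass with DHT (adjusted p = 0.07) or with both (0.2) with an estimated correlation. After thinning the median nearest to 0 was -0.60, which does not decide on depth, since thinning keeps the expected scaled values. Under one total per library the median nearest to 0 was -0.61. In the 4 comparisons the medians of all genes lay between -0.003 and 0.015 before that rescaling and between 0.005 and 0.042 after it. The list could thus hardly move, and the test alone does not decide. A scaling factor shifts all genes of a library alike, while the list lay apart from all genes, which argues against the authors' scaling. A difference in culture or selection of the shERF population cannot be told apart from lower ERF, since each hairpin was present in 1 population. The list score varied by an SD of at most 0.14 within groups and moved by at most 0.40 with dox, against at least 0.49 with shERF, which bears on plating alone. Lower ERF may be a cause and was not tested apart from the population.

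Each remaining result is a difference between groups that passed a test of the interaction, for lists with the preset and the estimated correlation. For dox by shERF without DHT these were 341 genes, KLK3 (-1.30, adjusted p = 1.0e-10), TMPRSS2 (-0.42, adjusted p = 0.0017) and the histone list (median -0.43, adjusted p = 0.033 with an estimated correlation). With DHT they were 926 genes, KLK3 (-1.12, adjusted p = 2.7e-09) and the histone list (median -0.30, adjusted p = 0.047 with an estimated correlation). For DHT by dox they were 1685 genes and the luminal prostate list (median 0.19, adjusted p = 0.04 with an estimated correlation). For DHT by shERF they were 4610 genes, the p53-response list (median -0.36, adjusted p = 0.04 with an estimated correlation), ERF (-0.27, adjusted p = 0.029), KLK3 (-0.64, adjusted p = 1.2e-05), KLK2 (-0.45, adjusted p = 0.0035), TMPRSS2 (-0.30, adjusted p = 0.0045) and FKBP5 (0.64, adjusted p = 2.1e-06).

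For the interactions, the remainders after additive effects were dealt afresh over the 12 libraries, in 100 arrangements with the real one included. The count for dox by shERF was reached in 3 of 100. The highest other arrangement called 1323 genes, several times the real 341, a sign of structure in the samples whose source was not tested. The dealing treats the 12 libraries as equally spread. Replicate pairs of shERF cells with dox had a chi-square per degree of freedom of 17.8 to 25.4, against at most 5.34 in shNT cells with dox. A random arrangement is therefore not excluded for this count. With DHT it was 1 of 100 (real 926, highest other 299), for DHT by dox 1 of 100 (1685 against 242) and for DHT by shERF 1 of 100 (4610 against 2023). The real count was thus the highest in each of these, under the same assumption of equal spread. The 12 comparisons of 3 against 3 libraries allow 10 splits each, too few for a share under 0.05; the real split was the 1 with the most genes in each. The highest other split called 1493 genes for dox in shERF cells (real 4394), 1 for shERF in vehicle (real 7884) and 0 in the other 10.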

How the results depend on the processing

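The voom fit and the thinning of reads were chosen only after the data had been seen; all other alternatives were planned. No paired analysis was possible because the replicate numbers follow accession order and pair no libraries. The planned edgeR and DESeq2 fits on recovered reads were not run; voom on those reads took their place and called 5242 genes for dox in shNT cells (4875 with limma on log2 values), 425 for dox by shERF (341) and 737 with DHT (926). ERG and ERF kept direction and call in their own hairpin's comparisons under all alternatives run (128 values). Over named genes, 13795 values kept direction and call, 58 gained and 71 lost the call and none reversed; over list tests the numbers were 3734, 107, 100 and 3. Of those 3, fry gave the test direction up to the ERG/ETS-linked list for DHT in shNT (median -0.11, adjusted p = 0.027) and to the p53-response list for shERF with dox and DHT (-0.12, 0.037). The mitochondrial-genome median for dox in shERF went from -0.14 to 0.18 without shERF_dox replicate 3 (0.023) and to -0.33 without shERF_dox replicate 1 (0.026). Of 272 list tests 111 passed, 44 with an estimated correlation and 190 with fry, which tests whether a list moves and not whether it moves more than other genes. Counts of changed genes stayed within 1.5 times in 275 values and moved further in 5. Dox in shERF cells gave 2718 genes when only its own 6 libraries entered the model. That left 4 residual degrees of freedom instead of 16, but the same restriction kept the other 15 comparisons within 1.5 times. The 4 interactions among these rest on more libraries and lost fewer degrees of freedom. Replicates of shERF cells with dox were the least alike (chi-square per degree of freedom 17.8 to 25.4). A spread shared over all groups may understate theirs, so the 4394 calls may be too many. With a replicate left out, dox by shERF ranged from 207 (without shNT_veh replicate 2) to 800 (without shERF_dox replicate 2), with 217 without shNT_veh replicate 1 and 220 without shNT_dox replicate 3. The DHT difference of the ETS-family score went from 0.07 to -0.02 under one total per library (adjusted permutation p = 0.35). The medians of all genes in the 4 DHT comparisons lay between -0.018 and 0.001 before that rescaling and between -0.119 and -0.076 after it. A score is not compared with other genes, so it carries such a shared shift. For genes moved by dox read in shERF comparisons, restriction to 2-fold changes brought 2 sets past the threshold: genes that fell, with a median of 0.57 in shERF with dox and DHT (adjusted p = 2.2e-07), and genes that rose, with 0.34 in shERF with DHT (adjusted p = 3.0e-04). The same restriction, for genes that fell with dox under DHT, gave -0.01 in shERF with dox, where the test direction reversed (adjusted p = 0.31), and -0.13 in shERF vehicle (adjusted p = 0.29). With an estimated correlation, genes that fell with dox under DHT had -0.08 in shERF with dox (adjusted p = 0.14), not past the threshold; the cause was not tested. Depth limits low genes most, since 1 read was worth between 0.765 and 1.22 scaled units.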

Other observations

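The held-out test of BMP targets had its prediction written before those genes were seen, while ID1, ID3, ATOH8 and the kallikrein levels were chosen only after their values were seen. Without DHT, KLK3 mRNA went from 2315.0 in shNT vehicle to 11039.7 with dox, 19259.1 with shERF and 37258.3 with both, while KLK2, beside it in the kallikrein family, went from 141040.9 to 177163.5, 185357.6 and 205735.7, with its change with dox in shERF cells not past the test (adjusted p = 0.19). Reads shared by KLK2 and KLK3 were not separated.

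ID1, ID3 and ATOH8, known targets of bone morphogenetic protein (BMP) and SMAD signalling, were higher in shERF vehicle cells by log2 fold changes of 5.08, 3.55 and 4.06. The hypothesis that targets of this pathway rise together was tested on 7 held-out targets (ID2, ID4, SMAD6, SMAD7, SMAD9, HEY1 and MSX2), which were higher as a set in 3 of the 4 shERF comparisons. These tests were adjusted over the 4 comparisons alone, an easier threshold than that of the lists, which were adjusted over 272 tests. The adjusted p with an estimated correlation was 0.021 in vehicle and 0.0063 with dox. It was 0.032 with dox and DHT, and 0.51 with DHT alone, where the median was 0.00. Without adjustment the camera p was 0.01 in vehicle, 0.0016 with dox and 0.024 with dox and DHT. Of the 7, 5, 3, 5 and 5 were called higher and 1, 2, 0 and 0 lower in vehicle, DHT, dox and both. ID2 rose by 2.59, 2.11, 2.82 and 2.55 in vehicle, DHT, dox and both, MSX2 by 1.38, 0.93, 1.19 and 0.91, and HEY1 passed in none. ID4 was lower in vehicle (-0.35) and with DHT (-0.67), and SMAD9 with DHT (-0.23). BMP signalling may therefore be higher in shERF cells, as a hypothesis; a difference between the selected populations was not separated from lower ERF.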
